A study of Mus musculus with 18 samples.

How the data were processed

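RNA sequencing libraries were analysed from 18 mouse samples in 6 groups of 3. The groups were HM-1 cells and ID8 cells in culture and intradermal HM-1 tumors, each as controls and as samples labelled Cd276KO. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit from cells or frozen tumors, and libraries were made by a standard Illumina procedure whose kit and strand setting are not given in the sources used here. Per the submitters' processing notes, the tools were Trim Galore, STAR and HTSeq and the genome build was GRCm38 (mm10), with no versions, annotation release or counting mode given. The deposited values were whole-number read counts per gene, not normalized, in 1 table with a column for each sample. The series design text says that the authors compared 3 control with 3 knockout samples with DESeq2, and their fold changes were not used here.

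The table held 54752 genes under versioned Ensembl identifiers, of which 20189 had no count in any library. Symbols and coordinates were taken from the GENCODE M21 annotation of GRCm38, where 53861 identifiers matched with their version and 54723 without it. A symbol was shared with another gene in 203 cases, and identifiers were kept apart in all tests. Total counts ranged from 17349082 to 30959773 per library. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and counts of near-identical gene copies are uncertain.

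Groups and replicate numbers came from the sample titles. Libraries of a group were first compared by a chi-square value per gene of their counts. The lowest was 1.62, above the 1 that sampling noise alone gives, so no library was taken as a second run of another. This cannot tell separate cultures or tumors from repeat preparations of 1 sample. Each library counted as 1 replicate by its label. Levels are counts per 1000000 of a library's total count (CPM), given as mean ± SD over n = 3. A difference was tested with edgeR 4.0.16 in R 4.3.3, by robust quasi-likelihood fits (glmQLFit and glmQLFTest) on the 6 libraries compared, after scaling by the trimmed mean of M values (TMM) and the filterByExpr filter on low counts. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all genes tested. The SE of a log2 fold change was its size divided by the square root of the F statistic. The difference between 2 knockout effects was tested as an interaction term over 12 libraries, with 1 spread estimated over all of them. Where all libraries of a group were at 0, the fold was given as a bound against a floor of 3 counts over the group, which covers counting error only, and a fitted fold of such a gene depends on the prior count of the fit.

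A set of 34 gene lists, for pathways and for cell types that a culture or tumor can hold, was fixed in advance. For each list the called members were counted over all genes and adjusted over the list alone, and lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. No camera call of the 3 knockout comparisons held with an estimated correlation.

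The genes to be named were set by rule. Cd276, Ccl2, Ccr2, Mrc1, Cd8a, Ifng and Stat3 were always reported. In each knockout comparison the 6 higher and 6 lower genes with the largest fold changes were taken among called genes with a mean of at least 5 CPM whose 3 values in one group lay on one side of the 3 in the other, which chance alone gives for 10% of genes. Predicted Gm genes, Rik clones, pseudogenes, immunoglobulin and T cell receptor segments and genes without a symbol were left out of this choice. Each list added its 2 called members with the largest fold changes, and each interaction its 3 highest and 3 lowest genes with a mean of at least 5 CPM. The text describes part of the genes taken, and any gene outside the rule is said to have been chosen after its values were seen.

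The tests were run on simulated counts with the means, spread and library sizes of each comparison, in which 200 genes were changed by known folds, 50 at each fold. In the simulation of HM-1 cells over 12457 genes, edgeR recovered 28% of genes changed 1.5-fold, 76% at 2-fold, 100% at 4-fold and 98% at 8-fold, and 3.8% of its calls were false. For ID8 cells over 12932 genes the shares were 80%, 94%, 98% and 98%, with 6.6% false. For tumors over 15345 genes they were 0%, 16%, 70% and 80%, with 6.7% false. DESeq2 1.42.0 gave 13.3%, 7.7% and 37.5% false calls in these 3 simulations. Each simulation was 1 draw with genes independent of each other. None held an outlying library, a shift shared by many genes or a larger share of changed genes, so these percentages may not carry over to the data.

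The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined. The alternatives were DESeq2, relative log and upper-quartile scaling, no filter, a filter of 10 counts in every library of a group, a block for the replicate number, 1 fit over all 18 libraries, limma voom with sample quality weights, and leaving out each library. Gene lists without HM-1 control library 1 and without control tumor library 3 were added after the data were seen, as were the tests per chromosome.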

Results

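The effect of losing B7-H3, a cell surface protein of the B7 immune checkpoint family encoded by Cd276, was examined in mouse ovarian cancer cells and in the tumors they form. HM-1 is a mouse ovarian cancer cell line that grows in immunocompetent B6C3F1 hybrid mice, and ID8 is a line derived from mouse ovarian surface epithelium. RNA was sequenced from both lines in culture and from intradermal HM-1 tumors collected on day 10 after inoculation of 1000000 cells. Each came from control cells and from cells labelled Cd276KO, with 3 libraries in each of 6 groups. Total counts per library were 17631035 to 25354150 in HM-1 control cells and 19393907 to 20945275 in HM-1 cells labelled Cd276KO. They were 26325938 to 30959773 in ID8 controls and 23602885 to 28089793 in ID8 cells labelled Cd276KO. Control tumors had 19181652 to 24711051 and tumors labelled Cd276KO 17349082 to 23488280. The labels call the libraries of a group biological replicates but do not say how many clones, cultures or mice they came from, so p-values measure the spread between these samples. HM-1 control library 1 stood apart from libraries 2 and 3 of its group, with a chi-square per gene of 71.3 and 69.9, against 1.62 between libraries 2 and 3. Control tumor library 3 stood apart from control tumors 1 and 2 with values of 149 and 90.5, against 45.4 between those 2.

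In HM-1 cells, Cd276 fell from 86.4 ± 10.6 CPM in controls to 46.6 ± 1.53 CPM in libraries labelled Cd276KO (SD, n = 3 per group), a log2 fold change of -0.85 (SE 0.10, adjusted p = 0.00146, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cd276 was thus still expressed, at 47.2, 47.7 and 44.8 CPM in these 3 libraries, and gene-level counts do not show which exon was targeted. Ccl2, the chemokine that draws monocytes through the receptor Ccr2, fell from 15.8 ± 2.66 to 0.10 ± 0.102 CPM (log2 fold change -7.17, SE 0.40, edgeR adjusted p = 7.75e-05), or -8.11 without library 2 labelled Cd276KO. Stat3, a transcription factor of cytokine signalling, fell from 74.4 ± 13.9 to 40.4 ± 2.26 CPM (log2 fold change -0.84, SE 0.14, edgeR adjusted p = 0.00589). Mrc1, the mannose receptor used as a marker of alternatively activated macrophages, rose in these cultured cancer cells from 17.6 ± 2.42 to 53.5 ± 2.88 CPM (log2 fold change 1.64, SE 0.11, edgeR adjusted p = 0.00015). Ccr2 had no count in HM-1 cultures. The T cell genes Cd8a and Ifng were too low to test, at 0.0821 ± 0.0739 and 0.0171 ± 0.0296 CPM in libraries labelled Cd276KO. On GRCm38, Cd276 (ENSMUSG00000035914.11) lies on chromosome 9 from 58524298 to 58555437 on the minus strand. Ccl2 (ENSMUSG00000035385.5) lies on chromosome 11 from 82035571 to 82037453 on the plus strand. Stat3 (ENSMUSG00000004040.16) lies on chromosome 11 from 100885098 to 100939540 on the minus strand. Mrc1 (ENSMUSG00000026712.3) lies on chromosome 2 from 14229392 to 14332057 on the plus strand. All 4 are annotated as protein-coding.

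**Figure D1:**
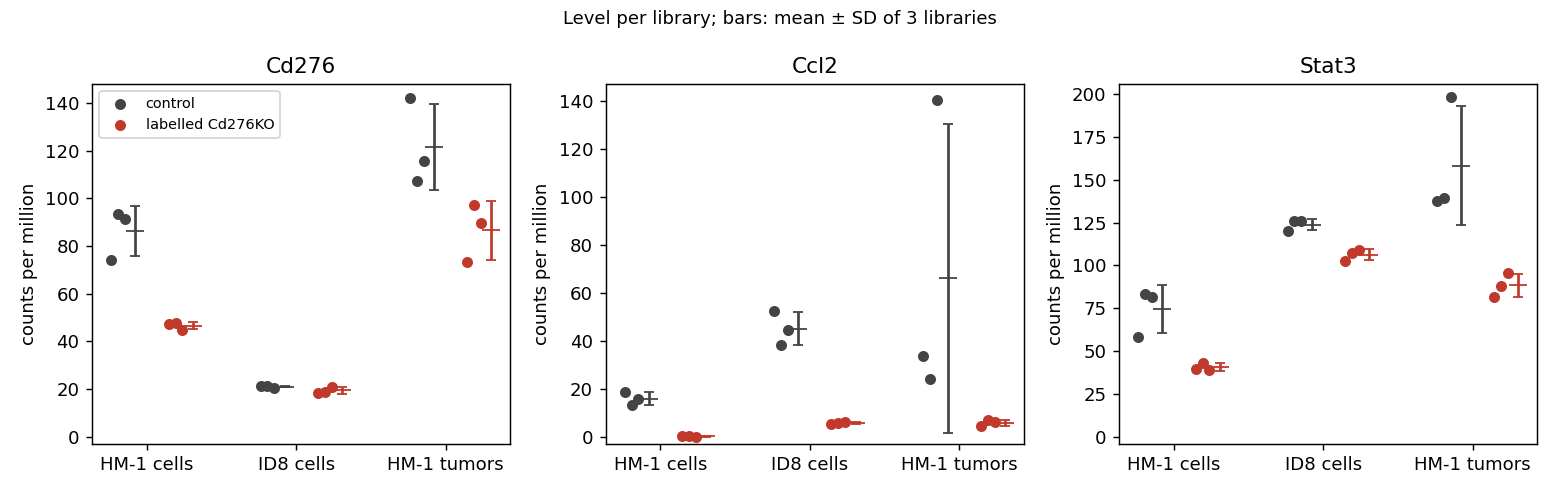
CPM of Cd276, Ccl2 and Stat3 (vertical axes) in each of the 18 libraries, by group (horizontal axes), with points for libraries and the mean ± SD of 3. Cd276 was 86.4 and 46.6 CPM in HM-1 control and Cd276KO cells but 20.9 and 19.4 CPM in the ID8 groups, while Ccl2 was lower in libraries labelled Cd276KO in both lines and in tumors.

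Several genes that HM-1 control cells expressed were not detected in the libraries labelled Cd276KO. Ckap4, which encodes a membrane protein of the endoplasmic reticulum, was at 107 ± 3.28 CPM in controls and at 0 in the other group, at least 2064-fold lower. Perp, a p53-induced component of desmosomes, was at least 304.6-fold lower and Xlr, a member of an X-linked gene family with several similar copies, at least 226.4-fold lower. Gem, a Ras-related GTPase, fell from 85.6 ± 2.9 to 0.0684 ± 0.0782 CPM. The log2 fold change was -10.16 for Gem, or -11.41 without library 2 labelled Cd276KO. The neurofilament gene Nefl and Trim44 had 1 and 2 counts in the libraries labelled Cd276KO, and their control level was 1465 times (95% counting interval 263 to 57900.0) and 1046 times (289 to 8638) as high. Among the genes that rose, Hnf4a, a nuclear receptor of liver and gut epithelium, went from 2.80 ± 0.759 to 25.2 ± 1.40 CPM (log2 fold change 3.18, SE 0.18). The chloride channel accessory genes Clca3a1 and Clca3b, similar copies whose reads can be shared, rose by 2.69 (SE 0.16) and 3.66 (SE 0.22) on the log2 scale. The trefoil peptide gene Tff1 rose by 2.62 (SE 0.18), the ion channel gene Trpa1 by 2.82 (SE 0.19) and the vomeronasal receptor gene Vmn2r26 by 3.70 (SE 0.13). Of 12457 genes tested by edgeR, 3452 were called, 1450 higher and 2002 lower, with 281 and 714 of these over 2-fold. Of the lower genes, 30 had no count in the libraries labelled Cd276KO. The count was 7491 without control library 1, and 1741, 1815 and 1725 without library 1, 2 or 3 labelled Cd276KO. Limma voom with sample quality weights called 7559.

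Antigen presentation genes of the MHC class I list fell in HM-1 cells labelled Cd276KO, with 10 of 16 tested members lower and Calr alone higher (log2 fold change 0.61). The counts were the same adjusted over the list alone. H2-D1 fell from 298 ± 52.2 to 89.8 ± 4.57 CPM (log2 fold change -1.69, SE 0.14) and H2-T23 from 27.0 ± 3.01 to 8.14 ± 0.541 CPM (-1.69, SE 0.12), both from a family of similar genes. The list had a median of -0.62 and a camera adjusted p of 0.00614, against an adjusted p = 0.540 with an estimated correlation. Among targets of NF-kB, the transcription factor of inflammatory signalling, 11 of 19 were lower and Tnfaip2 and Icam1 higher, the same counts adjusted over the list alone. The survival gene Birc3 fell by 6.03 (SE 0.37) and the adhesion gene Vcam1 fell by 1.79 (SE 0.15) on the log2 scale (camera adjusted p = 0.0376, adjusted p = 0.540 with an estimated correlation). Among p53 targets, 9 of 19 were lower, 10 adjusted over the list alone, and 1, Gdf15, was higher by either count. Mdm2, the ubiquitin ligase that limits p53, fell from 268 ± 28.6 to 149 ± 3.95 CPM (camera adjusted p = 0.00358, adjusted p = 0.292 with an estimated correlation). Epithelial genes were lower in 7 of 12 and higher in 1, Krt19, by either count. The tight junction gene Cldn3 (log2 fold change -4.40, SE 0.56, with 2 counts in libraries labelled Cd276KO and a ratio of 24.4, 95% counting interval 6.45 to 207) and the desmosome gene Dsp (-4.20, SE 0.39) led them, with a camera adjusted p of 0.0126 and an adjusted p = 0.540 with an estimated correlation. Genes of cholesterol and fatty acid synthesis were lower in 8 of 24, 9 adjusted over the list alone, among them Fdft1 (-0.79, SE 0.11) and Insig1 (-0.65, SE 0.09). The camera adjusted p was 0.0269, with an adjusted p = 0.540 with an estimated correlation. Without control library 1 the camera adjusted p was 0.0087 for MHC class I, 0.0182 for NF-kB, 0.00097 for p53 and for cholesterol genes. It was 0.0637 for epithelial genes, which ended that call, and with an estimated correlation the adjusted p = 0.641 for NF-kB and 0.369 for the other 3. Calr, Tnfaip2, Icam1, Gdf15 and Krt19 were named after their values were seen.

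Other lists in HM-1 cells moved in both directions or missed the set test. Chemokines and myeloid growth factors had 9 of 18 members lower and 4 higher, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.154). Cxcl3, a neutrophil-attracting chemokine, fell from 430.5 ± 68.9 to 24.1 ± 0.887 CPM, while its relatives Cxcl1 and Cxcl2 rose by 1.74 (SE 0.22) and 1.16 (SE 0.19) on the log2 scale. Cxcl1 and Cxcl2 were named after their values were seen, like the other higher members, Ccl9 and Tslp and, over the list alone, Il33. Mesenchymal and matrix genes had 8 of 23 lower and 3 higher by either count (Mmp14, Itgb3 and Tgfbi, named after their values were seen), with a camera adjusted p of 0.236. The matrix glycoprotein gene Tnc fell from 376 ± 108 to 6.04 ± 0.357 CPM (log2 fold change -5.92, SE 0.26). Cell cycle genes had 6 of 32 higher and 2 lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.146). The mitotic regulator gene Foxm1 rose from 138 ± 28.5 to 265 ± 5.54 CPM, and the lower members, Cdc45 and, over all genes alone, Tyms, were named after their values were seen. Interferon response genes were higher in 4 of 22 (Cxcl10, Gbp2, Oasl2 and Dhx58) and lower in 4 (Cmpk2, Rsad2, Ddx58 and Usp18), with Irf1 a further lower one adjusted over the list alone. The list's median was 0.04, or -0.02 with upper-quartile scaling (camera adjusted p = 0.786). Cmpk2 lost its call without library 1 or 3 labelled Cd276KO (edgeR adjusted p = 0.0638 and 0.0617), and the members other than Cxcl10 and Cmpk2 were named after their values were seen. Of 4 tested mesothelial and ovarian epithelial genes, 3 rose by either count. Msln, which encodes the surface antigen mesothelin, rose from 13.1 ± 1.19 to 46.1 ± 3.03 CPM. Gata6 rose by 1.29 (SE 0.22) and Podxl, named after its value was seen, by 0.57 (SE 0.16) on the log2 scale. Gata6 lost its call in a fit over all 18 libraries (edgeR adjusted p = 0.165), as did Cmpk2 (0.117). Among immune checkpoint genes, 4 of 11 were lower and 1 higher, by either count (camera adjusted p = 0.281). Tigit, a lymphocyte inhibitory receptor gene, fell in these cultures from 19.5 ± 0.362 to 6.41 ± 0.986 CPM (log2 fold change -1.56, SE 0.12). The other called members were Icosl (-1.57, SE 0.21) and, named after their values were seen, Cd274 (-1.12, SE 0.26), Lgals9 (-0.57, SE 0.09) and Havcr2 (0.66, SE 0.13). Fold changes in this paragraph are from the edgeR quasi-likelihood test.

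**Figure D2:**
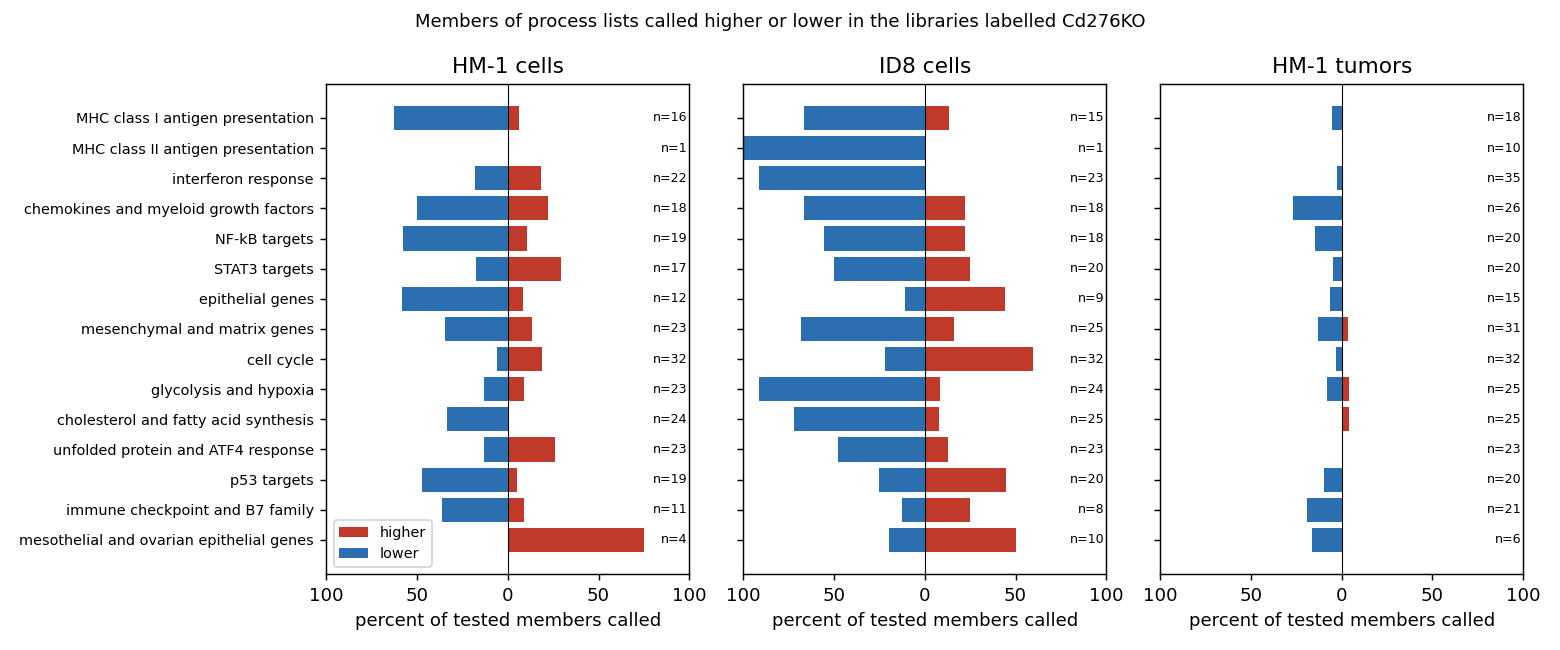
Percent of the tested members of 15 process lists (vertical axis) that were called higher (to the right) or lower (to the left) in libraries labelled Cd276KO (horizontal axis, percent of tested members), in HM-1 cells, ID8 cells and HM-1 tumors, with the number of tested members at the right. Interferon response genes were lower for 21 of 23 tested members in ID8 cells, against 4 lower and 4 higher of 22 in HM-1 cells.

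In ID8 cells, Cd276 was not lower in libraries labelled Cd276KO, with 20.9 ± 0.299 CPM in controls and 19.4 ± 1.45 CPM in the other group (n = 3 each, log2 fold change -0.04, SE 0.08, adjusted p = 0.692, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Gene-level counts therefore do not check the label of this line, and the groups are called by their labels throughout. Ccl2 fell from 45.0 ± 6.98 to 5.58 ± 0.495 CPM (log2 fold change -2.94, SE 0.12, edgeR adjusted p = 4e-13). Mrc1 rose at a low level, from 0.0921 ± 0.0479 to 1.11 ± 0.293 CPM (3.58, SE 0.44, edgeR adjusted p = 2.83e-07). Stat3 had 124 ± 3.16 and 106 ± 3.14 CPM (-0.14, SE 0.06, edgeR adjusted p = 0.0295). That call ended without control library 2 (0.0564) or 3 (0.0728) or without library 1 (0.139) or 2 (0.0658) labelled Cd276KO, with no filter on low counts (0.0793) and in a fit over all 18 libraries (0.538). Ccr2, Cd8a and Ifng had no count in either ID8 group.

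Among the genes that fell in ID8 cells labelled Cd276KO, Tmem35a, at 29.8 ± 1.80 CPM in controls, had no count in the other group and was at least 738.8-fold lower. Ly6e, with 2 counts left, fell by 9.34 (SE 0.24) on the log2 scale, a ratio of 759 (95% counting interval 209.9 to 6275). The smooth muscle actin gene Acta2 fell from 16.1 ± 1.81 to 0.0379 ± 0.0358 CPM (log2 fold change -8.48, SE 0.28), which rests on 3 counts, a ratio of 396 with a 95% counting interval of 135 to 1922, and was -9.29 without library 2 labelled Cd276KO. The actin-bundling gene Fscn1 fell from 104 ± 8.60 to 0.436 ± 0.209 CPM (-7.77, SE 0.14) and Col5a2, a fibrillar collagen gene, from 173.5 ± 5.68 to 0.773 ± 0.139 CPM (-7.74, SE 0.10), and Glipr1 fell by 7.50 (SE 0.25). Gnai1, an inhibitory G protein subunit, rose from 2.48 ± 0.378 to 75.9 ± 3.96 CPM (log2 fold change 5.02, SE 0.10). The RNA-binding gene Lin28a (4.81, SE 0.15), the protease gene Pcsk5 (4.70, SE 0.13), the imprinted gene Peg3 (4.68, SE 0.14), the tetraspanin gene Tspan7 (4.68, SE 0.18) and the Wnt ligand gene Wnt2 (4.29, SE 0.14) also rose. Of 12932 genes tested by edgeR, 7849 were called, 3798 higher and 4051 lower, with 385 and 1043 over 2-fold. Of the lower genes, 31 had no count in the libraries labelled Cd276KO. A single fit over all 18 libraries, which estimates 1 spread for cultures and tumors, called 4260.

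Interferon response genes fell in ID8 cells labelled Cd276KO, where 21 of 23 tested members were lower, by either count, and the median log2 fold change was -1.83. Lgals3bp fell from 5.56 ± 0.436 to 0.214 ± 0.0622 CPM and the antiviral gene Oas1a from 1.38 ± 0.372 to 0.026 ± 0.0228 CPM, the latter from 2 counts (ratio 50.9, 95% counting interval 13.8 to 425). The list had a camera adjusted p of 2.14e-07 and an adjusted p = 0.201 with an estimated correlation. MHC class I genes were lower in 10 of 15 and higher in 2 (H2-K1 and Pdia3, named after their values were seen) by either count. The peptide transporter gene Tap1 fell by 3.35 (SE 0.19) and Tap2 fell by 3.79 (SE 0.22) on the log2 scale (camera adjusted p = 0.0171, adjusted p = 0.453 with an estimated correlation). Glycolysis and hypoxia genes were lower in 22 of 24 and higher in 2 (Car9 and Egln3, named after their values were seen), by either count. The mitophagy receptor gene Bnip3 fell from 19.1 ± 1.81 to 0.194 ± 0.0563 CPM and Pdk1, the kinase that limits pyruvate oxidation, from 103 ± 1.64 to 26.7 ± 1.36 CPM (camera adjusted p = 5.3e-07, adjusted p = 0.262 with an estimated correlation). Chemokines and myeloid growth factors were lower in 12 of 18 and higher in 4 by either count (camera adjusted p = 0.00142, adjusted p = 0.237 with an estimated correlation). The neutrophil chemokine gene Cxcl5 fell from 21.6 ± 2.94 to 0.140 ± 0.0114 CPM, and the 4 higher members, named after their values were seen, were Cx3cl1, Il33, Lif and Tgfb1. Genes of cholesterol and fatty acid synthesis were lower in 18 of 25, or 19 adjusted over the list alone, and higher in 2 (Idi1 and Insig1, named after their values were seen). Among them Hmgcs1, an early enzyme of the pathway, fell from 424 ± 16.7 to 176 ± 9.95 CPM and Nsdhl from 60.3 ± 2.17 to 22.0 ± 0.225 CPM (camera adjusted p = 0.000435, adjusted p = 0.201 with an estimated correlation).

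The markers of cell state of the ID8 line also shifted. Mesenchymal and matrix genes were lower in 17 of 25, or 18 adjusted over the list alone, and higher in 4 (Cdh2, Sparc, Ccn1 and Ccn2, named after their values were seen). Twist2, a transcription factor gene of mesenchymal cells, was at least 32.76-fold lower (camera adjusted p = 0.000187, adjusted p = 0.237 with an estimated correlation). Epithelial genes were higher in 4 of 9 and lower in 1, by either count. Cldn3 rose from 6.10 ± 1.38 to 58.2 ± 2.22 CPM and Cdh1, the epithelial cadherin gene, fell from 9.96 ± 0.744 to 1.99 ± 0.172 CPM (camera adjusted p = 0.035, adjusted p = 0.486 with an estimated correlation). The other higher members, named after their values were seen, were Krt18, Esrp2 and Dsp. Mesothelial and ovarian epithelial genes were higher in 5 of 10 and lower in 2, by either count. Lrrn4 rose from 15.1 ± 0.977 to 131 ± 8.58 CPM and Podxl from 21.7 ± 0.253 to 115 ± 6.50 CPM (camera adjusted p = 0.04, adjusted p = 0.237 with an estimated correlation). Its other called members, named after their values were seen, were Upk3b, Gata6 and Wt1, higher, and Bnc1 and Cpe, lower. Cell cycle genes were higher in 19 of 32 and lower in 7, or 21 and 7 adjusted over the list alone. The lower ones included Ccne1 and E2f1, genes of S phase entry, at -1.0 (SE 0.12) and -0.88 (SE 0.07) on the log2 scale (camera adjusted p = 0.0129, adjusted p = 0.486 with an estimated correlation). Fold changes in this paragraph are from the edgeR quasi-likelihood test.

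The response to the Cd276KO label differed between the cell lines for 5747 of 14208 genes in an edgeR interaction test. Of these, 2807 had a higher and 2940 a lower log2 fold change in ID8 than in HM-1 cells. Cd276 itself was among them, with a difference of 0.80 (SE 0.12, edgeR adjusted p = 0.000232). So were Ccl2 at 4.23 (SE 0.50, edgeR adjusted p = 2.41e-05, 5.19 without HM-1 library 2 labelled Cd276KO), Mrc1 at 1.92 (SE 0.43, edgeR adjusted p = 0.00317) and Stat3 at 0.68 (SE 0.15, edgeR adjusted p = 0.003). Interferon response genes had lower fold changes in ID8 cells for 17 of 26 tested members and higher ones for none, or 19 and none adjusted over the list alone. The median difference was -1.83, and the camera call (adjusted p = 3.94e-07) also held with an estimated correlation (adjusted p = 0.0305). Glycolysis and hypoxia genes differed the same way for 19 of 24, against 2 the other way (Car9 and Egln3, named after their values were seen), with a median of -0.63, a camera adjusted p of 1.01e-05 and an adjusted p = 0.298 with an estimated correlation. Over 11386 genes tested in both lines, 598 were lower in both, against 518.8 for independent lists (one-sided Fisher exact p = 4.19e-06), and 313 were higher in both, against 379.2 (p = 1). In all, 911 genes moved the same way and 1003 in opposite ways, against 898 and 896.2 for independent lists. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.027 (Pearson) and -0.087 (Spearman). Fisher's test also takes genes as independent, so its p-values in this paragraph can be too small where genes move together. With calls over 2-fold, 99 genes were lower in both lines, against 27.7 (one-sided Fisher exact p = 2.3e-30), and 5 higher, against 2.5 (p = 0.0997). The 5 were Mrc1, Atoh8, Atp6v0e2, Sptb and Lrtm2, all but Mrc1 named after their values were seen. Another 65 moved in opposite ways, against 16.6.

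In HM-1 tumors on day 10, part of the neutrophil, macrophage and chemokine genes were lower in the group labelled Cd276KO. Ccl2 was at 66.0 ± 64.4 CPM in control tumors (33.8, 24.2 and 140) and at 5.76 ± 1.27 CPM in tumors labelled Cd276KO (n = 3 each, log2 fold change -3.52, SE 0.74, adjusted p = 0.0476, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cd276 was at 122 ± 18.1 and 86.6 ± 12.2 CPM, which did not pass the test (log2 fold change -0.45, SE 0.14, edgeR adjusted p = 0.105, DESeq2 adjusted p = 0.0445, edgeR over all 18 libraries 0.00503). Stat3, at 158 ± 34.5 and 88.4 ± 6.78 CPM, missed it too (-0.81, SE 0.19, edgeR adjusted p = 0.0567), but passed without control tumor 3 (-0.57, edgeR adjusted p = 0.0135), with no filter on low counts (edgeR, 0.0198), with DESeq2 (0.00158), with voom weights (0.00943) and in a fit over all 18 libraries (0.000776). The fit over all 18 libraries estimates 1 spread for cultures and tumors, which can understate that of tumors. Mrc1 was at 160 ± 36.8 and 101 ± 43.8 CPM (edgeR adjusted p = 0.271) and Ccr2 at 18.1 ± 19.8 and 22.9 ± 15.2 CPM (edgeR adjusted p = 0.815). Cd8a, at 0.234 ± 0.148 and 0.230 ± 0.351 CPM, and Ifng, at 0.0135 ± 0.0234 and 0.0384 ± 0.0666 CPM, were too low to test at this depth. The call of Ccl2 ended without control tumor 1 (edgeR adjusted p = 0.0553) or 2 (0.0523), and without tumor 1, 2 or 3 labelled Cd276KO (0.178, 0.146 and 0.205), and with no filter on low counts (0.183), while without control tumor 3 its log2 fold change was -2.25 (0.00355).

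Perp, Gem and the desmosome gene Dsp, which fell in cultured HM-1 cells, also fell in the tumors labelled Cd276KO. Gem went from 191.5 ± 173 to 1.80 ± 0.625 CPM (log2 fold change -6.71, SE 0.83), Perp from 13.3 ± 19 to 0.0334 ± 0.0299 CPM (-8.41, SE 1.79), and Dsp from 12.9 ± 13 to 0.129 ± 0.113 CPM (-6.54, SE 1.14). Perp had 2 counts in tumors labelled Cd276KO, a ratio of 343 with a 95% counting interval of 94.7 to 2840.0. Tmem163 fell by 6.65 (SE 0.74), Fam83g fell by 6.01 (SE 0.72) and Fbxl16 fell by 5.89 (SE 0.72) on the log2 scale. Without control tumor 3 the log2 fold change was -5.81 for Perp, -5.57 for Gem, -5.21 for Dsp, -5.75 for Tmem163, -5.14 for Fam83g and -5.27 for Fbxl16. Without tumor 2 labelled Cd276KO it was -7.13 for Dsp and -6.87 for Fbxl16. Skin keratinocyte genes, a list that holds Perp, took 0.043% of counts in control tumor 3 and at most 0.00163% in the others. Several genes of striated muscle were among the higher ones. Xirp1 went from 0.112 ± 0.151 to 21.2 ± 16.2 CPM (7.42, SE 1.27) and the fast myosin gene Myh2 from 0.139 ± 0.197 to 15.2 ± 9.96 CPM (6.67, SE 1.02). Csrp3 (6.04, SE 0.95), Hspb7 (5.42, SE 1.03) and Myo18b (5.23, SE 1.02) rose too, as did R3hdml (5.04, SE 0.73). Without control tumor 1 the log2 fold change was 9.41 for Xirp1, 8.95 for Myh2, 6.77 for Hspb7 and 7.01 for Myo18b, and without control tumor 2 it was 5.86 for R3hdml. Limma voom with sample quality weights ended the calls of Xirp1 (adjusted p = 0.127), Csrp3 (0.112), Hspb7 (0.115), Myo18b (0.0503) and Myh2 (0.0618). Of 15345 genes tested by edgeR, 826 were called, 338 higher and 488 lower, with 177 and 369 over 2-fold. Calls in tumors depended on single libraries, and their number was 353, 263 and 1685 without control tumor 1, 2 or 3. Without tumor 1 labelled Cd276KO, edgeR called 1 gene (Abra, chosen after its value was seen), and without tumor 2 or 3 it called 0. In these 3 fits 2829, 2851 and 2410 genes had an unadjusted p under 0.05 and DESeq2 called 1436, 1516 and 1102. All 826 genes kept their sign in them, and the 44 named genes that were called had an edgeR adjusted p of 0.0701 to 0.178, 0.0762 to 0.159 and 0.137 to 0.211. Without control tumor 1, 22 of the 44 kept their call (edgeR adjusted p of the others 0.0504 to 0.0802), and without control tumor 2, 14 did (0.0523 to 0.094). Without control tumor 3, 39 did, the others being Xirp1 (edgeR adjusted p = 0.0807), Csrp3 (0.0692), Hspb7 (0.095), Myo18b (0.0542) and Des (0.0651). With no filter on low counts, the calls of Xirp1 (0.105), Csrp3 (0.0866), Hspb7 (0.143), Myo18b (0.0782), Perp (0.174), Gem (0.0582) and Dsp (0.0666) ended.

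Some neutrophil and macrophage genes fell in tumors labelled Cd276KO. Of 13 tested neutrophil genes, 5 were lower, or 9 adjusted over the list alone, with a median log2 fold change of -2.37. The decoy receptor gene Il1r2 fell from 20.8 ± 8.08 to 3.01 ± 0.586 CPM (-2.77, SE 0.36) and the lectin gene Clec4d from 11.4 ± 7.37 to 1.47 ± 0.708 CPM (-2.94, SE 0.63, or -2.22 without control tumor 3). The others were Mmp9 (-2.37, SE 0.40), a matrix protease gene, and, named after their values were seen, Csf3r and Trem1. Of 20 macrophage genes, 4 were lower, or 7 adjusted over the list alone, with a median of -0.65. The integrin gene Itgam fell from 34.0 ± 13.4 to 8.83 ± 2.63 CPM (-1.93, SE 0.37) and the Fc receptor chain gene Fcer1g from 56.7 ± 10.6 to 23 ± 5.84 CPM (-1.28, SE 0.23). The others, named after their values were seen, were Cd68 and Tyrobp. Genes of alternatively activated (M2-type) macrophages were lower in 5 of 19, or 8 lower and 2 higher (Retnla and Pltp) adjusted over the list alone. The arginase gene Arg1 fell from 138 ± 58.5 to 20.8 ± 7.84 CPM (-2.70, SE 0.44) and the chemokine gene Ccl22 from 76.2 ± 39.2 to 10.4 ± 2.20 CPM (-2.81, SE 0.43). Ccl17 fell by 1.86 (SE 0.35) on the log2 scale, and Msr1 and Ccl24, the others called, were like Retnla and Pltp named after their values were seen. Camera adjusted p was 6.5e-05 for neutrophils and for macrophages and 0.00711 for M2-type genes, against an adjusted p = 0.548 with an estimated correlation for each. By fry, which tests each list without setting it against other genes, the adjusted p was 0.148, 0.203 and 0.233. Without control tumor 3, neutrophil and macrophage genes had medians of -1.34 and -0.83 (camera adjusted p = 2.5e-05 and 2.2e-05, adjusted p = 0.428 and 0.549 with an estimated correlation), and 8 M2-type genes were called lower. Cultured HM-1 cells also carried genes of these lists. The neutrophil list took 0.000852% of counts in control cells and 0.0809% in control tumors, and the macrophage list 0.00735% and 0.201%. Of 4 neutrophil genes tested in culture, Mmp9 (-2.47, SE 0.37), Clec4d (-3.88, SE 0.43) and Il1r2 (-1.60, SE 0.28) fell and Ly6g rose in libraries labelled Cd276KO, and of 3 macrophage genes Cd68 fell (-0.51, SE 0.12). In culture Cd68 lost its call without control library 2 (edgeR adjusted p = 0.0502) or 3 (0.0545), without library 1 (0.0842) or 2 (0.0786) labelled Cd276KO and in a fit over all 18 libraries (0.0857), as did Mmp9 in that fit (0.0559). Ly6g was named after its value was seen. The monocyte and MHC class II lists did not pass the set test. Of 12 monocyte genes, 1, the coagulation factor gene F10, was lower (-1.61, SE 0.34, edgeR adjusted p = 0.0483), or 7 lower and 1 higher adjusted over the list alone, with a median of -1.62 (camera adjusted p = 0.163). That list took 0.405%, 0.507% and 0.392% of counts in control tumors and 0.535%, 0.718% and 0.582% in tumors labelled Cd276KO. Most of these counts were of Fn1, the fibronectin gene (log2 fold change 0.58, edgeR adjusted p = 0.109), named after its value was seen like the higher member, Hp. The 10 MHC class II genes had a median of -0.11 (camera adjusted p = 0.487). Skeletal muscle genes took 0.0178%, 0.120% and 0.127% of counts in the 3 tumors labelled Cd276KO and 0.0194%, 0.000586% and 0.000892% in control tumors. Without control tumor 1 the calls of Itgam (edgeR adjusted p = 0.0641) and Fcer1g (0.066) ended, and without control tumor 2 those of Arg1 (0.0568), Ccl22 (0.0569), Mmp9 (0.0614) and Clec4d (0.0607). Clec4d (0.0654), Ccl17 (0.0505) and F10 (0.0753) also lost their calls without control tumor 1, and Ccl17 (0.0708) and F10 (0.0792) without control tumor 2. No call in this paragraph held without any single tumor labelled Cd276KO, where edgeR adjusted p was 0.0701 to 0.211 over the named genes. With no filter on low counts Arg1 (0.0717), Ccl22 (0.0593) and Mmp9 (0.0512) lost their calls.

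**Figure D3:**
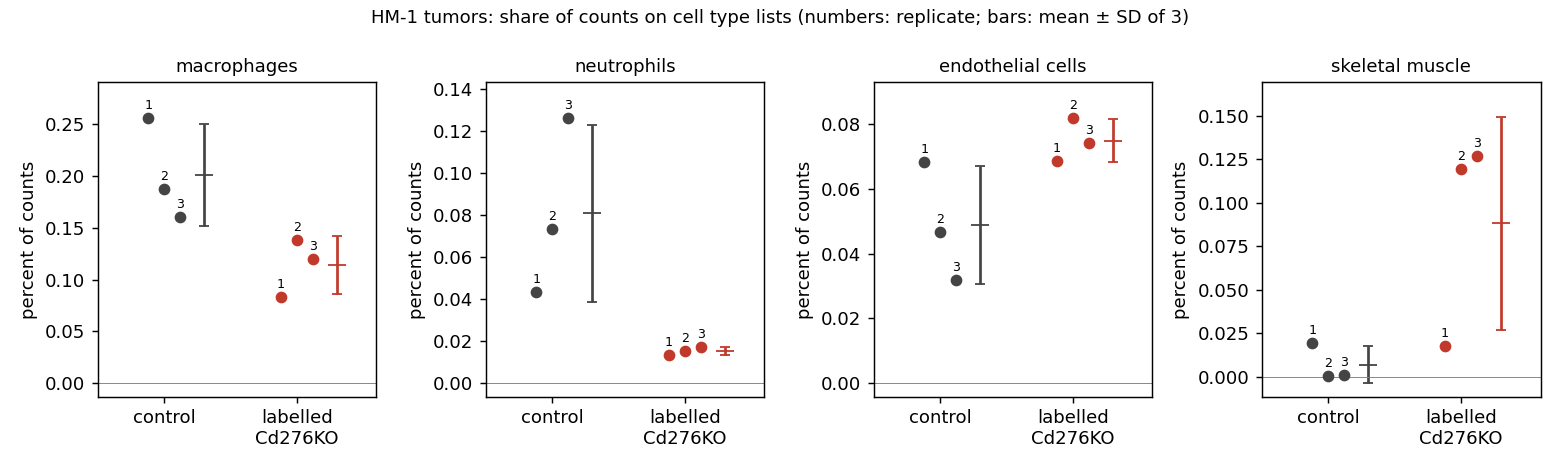
Percent of all counts (vertical axes) on the macrophage, neutrophil, endothelial and skeletal muscle lists in each control tumor and each tumor labelled Cd276KO (horizontal axes), with the replicate number beside each point and the mean ± SD of 3. Neutrophil genes took 0.043%, 0.073% and 0.126% of counts in control tumors and 0.014%, 0.015% and 0.017% in tumors labelled Cd276KO. Most of the rise of the mean endothelial share was of Plvap.

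Lists of interferon response, MHC class I, immune checkpoint and cytotoxic lymphocyte genes were also ranked lower by camera in tumors labelled Cd276KO. Interferon response genes had a median log2 fold change of -1.20 over 35 tested members (camera adjusted p = 6.21e-06, adjusted p = 0.548 with an estimated correlation), of which 1, Ifit2, was called. Ifit2 fell from 7.83 ± 1.5 to 2.95 ± 0.513 CPM (-1.37, SE 0.28), and no member was called adjusted over the list alone. MHC class I genes had a median of -0.76 over 18 (camera adjusted p = 0.0011, adjusted p = 0.548 with an estimated correlation), with 1 called, Nlrc5, the transactivator of this gene class, which fell from 26 ± 10.2 to 3.89 ± 1.72 CPM (-2.73, SE 0.44). Adjusted over the list alone 3 were called, with H2-K1 and H2-D1. Immune checkpoint genes were lower in 4 of 21, or 7 adjusted over the list alone (median -0.83, camera adjusted p = 0.000904, adjusted p = 0.548 with an estimated correlation). Tigit fell from 12.9 ± 1.22 to 1.46 ± 0.386 CPM (-3.10, SE 0.26) and the costimulatory ligand gene Cd80 from 16.5 ± 2.73 to 3.72 ± 0.778 CPM (-2.11, SE 0.24), and the others called were Cd274 and Havcr2. HM-1 cells in culture also expressed Tigit, at a higher level in control cells than in control tumors, and it fell there in libraries labelled Cd276KO. Cd274 also fell in those cultures, while Havcr2 rose. Of 8 cytotoxic lymphocyte and NK cell genes, 1, the granzyme gene Gzmb, was called, from 4.20 ± 2.73 to 0.203 ± 0.0328 CPM (-4.31, SE 0.62, or -3.57 without control tumor 3). The list had a camera adjusted p of 0.00324 and an adjusted p = 0.548 with an estimated correlation. Adjusted over the list alone 3 were called, with Eomes and Ccl5. Cultured HM-1 cells also carried genes of this list, which took 0.00564% of counts in control cells and 0.0037% in control tumors. Both members tested in culture, Eomes (-0.39, SE 0.09) and Ccl5 (-1.26, SE 0.29), fell there in libraries labelled Cd276KO (edgeR adjusted p = 0.0166 and 0.0185). Both missed without library 1 (edgeR adjusted p = 0.0798 and 0.0813) or 2 (0.0781 and 0.0821) labelled Cd276KO, Ccl5 without control library 2 (0.0543) and Eomes in a fit over all 18 libraries (0.0897). Of 12 T cell genes none was called by either count (median -0.66, camera adjusted p = 0.551), and they took 0.00766% of counts in control tumors and 0.00792% in tumors labelled Cd276KO. In HM-1 cultures this list took 0.0041% of counts in control cells and 0.00211% in libraries labelled Cd276KO. The tumor shares are thus not read from T cells alone. By fry the adjusted p was 0.261 for the interferon, 0.233 for the MHC class I, 0.0566 for the checkpoint, 0.0897 for the cytotoxic and 0.183 for the chemokine list. Chemokines and myeloid growth factors were lower in 7 of 26, or 13 lower and 3 higher (Cxcl5, Csf3 and Tslp) adjusted over the list alone. Cxcl3 fell from 177 ± 152 to 7.21 ± 3.18 CPM (-4.61, SE 0.79, or -3.59 without control tumor 3). That list had a camera adjusted p of 0.00254 and an adjusted p = 0.548 with an estimated correlation. Without control tumor 3 the interferon list had a median of -0.60 (camera adjusted p = 0.000303, adjusted p = 0.428 with an estimated correlation), with Ifit2, Gbp7 and Ddx58 lower and Bst2 and Usp18 higher. The MHC class I list, which took 0.786% of counts in control tumor 3 and 0.450% and 0.432% in control tumors 1 and 2, had a median of -0.37 without it (camera adjusted p = 0.000526, adjusted p = 0.428 with an estimated correlation), with Nlrc5, H2-K1, H2-D1, H2-T23 and H2-Q4 lower. Ccl5 was called there beside Gzmb. Fold changes here are from edgeR, and Gbp7, Ddx58, Bst2, Usp18, H2-T23, H2-Q4, H2-K1, H2-D1, Eomes, Ccl5, Cxcl5, Csf3, Tslp, Cd274 and Havcr2 were named after their values were seen. The calls of Tigit, Cd80 and Gzmb held without each single control tumor. Ifit2 (edgeR adjusted p) missed without control tumor 1 (0.0802) or 2 (0.0569), and Nlrc5 (0.056) and Cxcl3 (0.0568) without control tumor 2, and Cxcl3 with no filter on low counts (0.121). None held without any single tumor labelled Cd276KO (edgeR adjusted p = 0.0701 to 0.211 over the named genes).

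Blood vessel genes had few calls in tumors. Of 17 endothelial genes, 1 was called by either count, Plvap, which encodes the diaphragm protein of fenestrated endothelium and rose from 49.0 ± 18.4 to 311 ± 11.5 CPM (log2 fold change 2.71, SE 0.25, edgeR adjusted p = 0.0149). The list had a median of 0.09 (camera adjusted p = 0.317), or -0.26 without control tumor 3 (0.391). It took 0.0489% of counts in control tumors and 0.0748% in tumors labelled Cd276KO, and most of that rise was of Plvap. Cultured HM-1 cells also carried genes of this list, at 0.00831% of counts in control cells and 0.0117% in libraries labelled Cd276KO. The share is thus not read from blood vessels alone. Pericyte and smooth muscle genes had 1 of 13 called, or 3 adjusted over the list alone, with Rgs5 and Higd1b. The muscle filament gene Des rose from 17.4 ± 7.63 to 86.0 ± 33.7 CPM. The list had a median of 0.21 (camera adjusted p = 0.295), or -0.09 without control tumor 3 (0.938), where Higd1b alone was called. Skeletal muscle genes had a median of 3.35 over 17 members, with 1 called, Myh2, or 4 adjusted over the list alone, with Ttn, Neb and Ryr1 (camera adjusted p = 3.18e-06, adjusted p = 0.548 with an estimated correlation, fry adjusted p = 0.203). Rgs5, Higd1b, Ttn, Neb and Ryr1 were named after their values were seen. Fibroblast genes had a median of -0.58 over 18 with none called by either count, while camera ranked them in the other direction (adjusted p = 0.703), but without control tumor 3 the median was -1.06 and camera called them lower (camera adjusted p = 0.0237, adjusted p = 0.738 with an estimated correlation). Plvap kept its call without each single control tumor, Des lost it without control tumor 2 (0.0626) or 3 (0.0651) or with no filter on low counts (0.067) and Myh2 without control tumor 2 (0.0525) or with voom weights (0.0618). No call held without tumor 1, 2 or 3 labelled Cd276KO, where Plvap had an edgeR adjusted p of 0.0899, 0.0762 and 0.137.

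Most genes called in both HM-1 cells and HM-1 tumors moved in the same direction. Among 12288 genes tested in both, 291 were lower in both, against 67.1 for independent lists (one-sided Fisher exact p = 1.15e-138), and 151 higher in both, against 33.7 (p = 7.13e-66). In all, 442 moved the same way and 25 in opposite ways. Log2 fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.645 and a Spearman rho of 0.58. Fisher's test also takes genes as independent, so its p-values can be too small where genes move together. Of the 488 lower genes in tumors, 71 were not tested in cultured cells for low counts, and 65 of these were over 2-fold higher in control tumors than in control cells. That is nearly set by the filter, since a gene lower in tumors labelled Cd276KO passes it mostly through control tumors. Among the 338 higher genes 47 were not tested in cultured cells, and 3 of these were over 2-fold higher in control tumors. As tumors also hold RNA of host cells, a difference from cultures does not by itself show another response of the cancer cells. An edgeR interaction test over 15623 genes called 443 whose response differed between tumors and cells. The test estimates 1 spread for cultures and tumors, with a common biological coefficient of variation of 0.238. Fitted apart, it was 0.134 in HM-1 cells and 0.303 in tumors. Differences that come from tumors can thus be called too easily. Of these, 268 had a higher and 175 a lower log2 fold change in tumors. Mrc1 was among them at -2.29 (SE 0.40, edgeR adjusted p = 0.0112). Ccl2 at 3.71 (SE 1.21, edgeR adjusted p = 0.155), Cd276 at 0.39 (SE 0.20, 0.409) and Stat3 at 0.03 (SE 0.22, 0.989) were not. Ccl2 passed without control tumor 3 (4.88, edgeR adjusted p = 0.000926) and with DESeq2 (adjusted p = 0.00434). Immediate early and heat shock genes had lower fold changes in tumors for 4 of 15 (Fos, Fosb, Dnajb1 and Hsph1), or 8 lower and 1 higher (Jun) adjusted over the list alone (median -0.83, camera adjusted p = 0.000466, adjusted p = 0.172 with an estimated correlation). Interferon response genes had lower ones for 3 of 35 (Oasl2, Gbp2 and Cxcl10), or 6 adjusted over the list alone (median -0.89, camera adjusted p = 0.00147, adjusted p = 0.827 with an estimated correlation). Members of these lists were named after their values were seen. The count of 443 was 266 and 280 without HM-1 control library 2 or 3, 225, 244 and 229 without HM-1 library 1, 2 or 3 labelled Cd276KO, 227 without tumor 3 labelled Cd276KO, 913 without control tumor 3 and 953 with DESeq2.

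To see which lists differ between tumors and cultures, control tumors were compared with control cells in culture. RNA of host cells and a change in the cancer cells themselves cannot be told apart by this comparison. Macrophage genes were higher in tumors for 19 of 20 members (fitted median log2 fold change 10.27, or 9.33 with genes at 0 in cells set to their bound). MHC class II genes were higher for 10 of 10, endothelial genes for 17 of 17, pericyte and smooth muscle genes for 13 of 13 and fibroblast genes for 15 of 15. The counts were the same adjusted over each list alone. Interferon response genes were higher for 29 of 35, or 30 adjusted over the list alone (median 3.38, camera adjusted p = 2.41e-07), and glycolysis and hypoxia genes for 17 of 25, or 20 (median 1.40, camera adjusted p = 8.92e-06). Cell cycle genes were lower for 28 of 32, or 31 (median -1.23, camera adjusted p = 2.45e-12). The adjusted p with an estimated correlation was 0.304, 0.308 and 0.278 for these 3 lists, 0.372 for fibroblasts and 0.278 for the other cell types named here. Mrc1 was 3.04 higher on the log2 scale in tumors (SE 0.20, edgeR adjusted p = 0.000153) and Stat3 0.96 higher (SE 0.21, edgeR adjusted p = 0.00925), while Ccl2 at 1.94 (edgeR adjusted p = 0.0508) and Cd276 at 0.36 (edgeR adjusted p = 0.0982) did not pass the test. Of 14609 genes tested by edgeR, 6107 were called, 3689 higher and 2418 lower in tumors. Of the higher genes, 403 had no count in control cells. Upper-quartile scaling moved the median of all genes by 0.136 on the log2 scale and gave 4165 higher and 1701 lower genes, 71% of calls higher against 60.4%.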

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

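The tests for the same response in ID8 cells, for loss of a whole chromosome, for RNA of cultures labelled Cd276KO in a control library and for a lower share of all host cells were chosen only after the results they bear on were seen. The response to the Cd276KO label differed between HM-1 tumors and HM-1 cells for 443 genes by an edgeR interaction test, which estimates 1 spread for cultures and tumors. The highest differences of log2 fold changes (tumors minus cells) were 12.34 for Ckap4 (edgeR adjusted p = 0.000507), 7.94 for the muscle gene Csrp3 (0.0205) and 7.79 for Trim44 (0.000105). Ckap4 and Trim44 were nearly silent in cultures labelled Cd276KO but fell only by 1.85 (SE 0.38) and by 1.99 (SE 0.29) on the log2 scale in tumors. Ckap4 had no count in those cultures, so its fitted difference depends on the prior count of the fit. Tumors also hold RNA of host cells, so a difference from cultures does not by itself show another response of the cancer cells. The lowest differences were -4.83 for Tff1 (edgeR adjusted p = 0.00758), -4.67 for the serine protease gene Tmprss11b (0.000463) and -4.25 for the phosphatase gene Ptpn22 (0.000669), and Mrc1 was at -2.29 (0.0112). Ptpn22 rose in cultures labelled Cd276KO by 1.10 (SE 0.10) and fell in tumors by 3.18 (SE 0.47). Csrp3 missed the test without HM-1 control library 2 (edgeR adjusted p = 0.065) or 3 (0.085), without HM-1 library 1 (0.0527) or 3 (0.0586) labelled Cd276KO and with no filter (0.095), and Tff1 missed it with no filter (0.0549). Csrp3 was at 8.55 without control tumor 1 and 8.83 without HM-1 library 2 labelled Cd276KO, and Tff1 at -3.80 without control tumor 3.

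Between ID8 and HM-1 cells the response differed for 5747 genes by the same kind of test. Differences of log2 fold changes (ID8 minus HM-1) were 14.37 for Ckap4 (edgeR adjusted p = 6.31e-11), 12.84 for the protease inhibitor gene Spint2 (0.00286) and 12.71 for Perp (9.74e-10). Perp rose by 1.14 (SE 0.05) in ID8 cells and had no count in HM-1 cells labelled Cd276KO. They were -14.56 for Tmem35a (0.00331), -10.76 for Rnf219 (1.28e-08) and -9.26 for Ly6e (9.74e-10). Fitted differences depend on the prior count where a group is at 0, as for Ckap4, Spint2, Perp, Tmem35a and Rnf219. Spint2 was at or near 0 in both ID8 groups and Tmem35a in both HM-1 groups, and their calls ended (edgeR adjusted p = 1) without ID8 library 1 and without HM-1 library 2 labelled Cd276KO. Cd276 differed by 0.80, Ccl2 by 4.23, Mrc1 by 1.92 and Stat3 by 0.68, and interferon response genes had a median difference of -1.83.

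In HM-1 cells 23 genes on 11 chromosomes had at least 5 CPM in controls and under 0.1 CPM in libraries labelled Cd276KO, and 19 of them were also called lower in tumors (median log2 fold change -4.83). Deletions of several neighbouring genes were argued against as the whole cause, since 13% of the 23 (3 genes) had a silent neighbour among 9884 expressed genes, although 10000 random draws gave a mean of 0.096 and at most 4. Xlr and, named after their values were seen, 3830403N18Rik and Gm773 lay on the X chromosome between 53777118 and 56212881. All had no count in cultures labelled Cd276KO, and for them a shared local loss stays open. Loss of a whole chromosome was argued against as the cause of the silence, since the lowest median log2 fold change of a chromosome was -0.32 (quartiles -0.577 and -0.064). Other copy-number differences of whole chromosomes were argued against as that cause too, as the chromosome explained 3.32% of the variance of log2 fold changes and 18 of the 23 genes lay on chromosomes with medians of -0.10 to 0.05, although the other 5 (Gem, Fam83g, Nefl and, named after their values were seen, Gpx7 and Cyba) lay among the 9 chromosomes whose genes shifted as sets with an estimated correlation. A response to loss of Cd276 in both lines or in HM-1 cells alone and a difference between the clones or cultures behind the groups stay open, as the labels do not give the clones and Cd276 counts were not lower in ID8 cells, where the 7 of these genes expressed had a median of -0.03 (quartiles -0.222 and 0.076, 2 called lower).

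In tumors labelled Cd276KO, the macrophage and neutrophil genes had a median log2 fold change of -0.90 (quartiles -1.93 and -0.605, 33 genes). Control tumor 3 alone was argued against, since the median without it was -0.99 with 31 of 33 genes below 0. Dilution by skeletal muscle was argued against, as its genes took at most 0.127% of counts in a tumor labelled Cd276KO and 0.0194% in a control tumor. A lower share of all host cells alike was argued against, since endothelial and pericyte genes had a median of 0.09 (quartiles -0.287 and 0.237, 30 genes), 0.985 above the myeloid genes, and without control tumor 3 a median of -0.24 (quartiles -0.62 and -0.032), 0.748 above them (quartiles -1.306 and -0.678). A lower share of macrophages and neutrophils, alone or with fibroblasts, and lower expression within them or in the cancer cells stay open as hypotheses. Fibroblast genes had a median of -1.06 without control tumor 3 (quartiles -1.728 and -0.569, 18 genes). A lower share of host cells that differs between types stays open too. Xist, near 0 in HM-1 cultures (0.033 CPM in controls), had a log2 fold change of -0.55 (edgeR adjusted p = 0.573), or -0.90 without control tumor 3 (0.325). Variation between the tumors of a group was not excluded either, as no camera call held with an estimated correlation. The leukocyte gene Ptprc, chosen after its values were seen, was at 63.5, 41.0 and 32.1 CPM in control tumors. It was at 17.9, 39.1 and 31.9 CPM in tumors labelled Cd276KO, so the groups overlapped.

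HM-1 control library 1 differed from libraries 2 and 3 with an SD of log2 deviations of 0.531 over 12457 genes, against 0.204 between libraries 2 and 3. GC content and transcript length explained 36.83% of the variance of its deviations over 12454 genes, which is consistent with a bias of GC content or length as a candidate explanation. RNA of the ID8 line was argued against by a median of 0% of the ID8 level over 92 genes of ID8 cells. Of 7418 genes called between libraries 2 and 3 and the HM-1 cultures labelled Cd276KO, 47.2% lay on the side of those cultures in library 1. This near-even share does not point to RNA of those cultures. It cannot exclude an admixture, as GC content and length explained much of the deviations of the same library. No biological explanation was tested, as the labels put the 3 libraries in 1 group.

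Other splits of the same libraries into groups of 3 were tested with edgeR for each count of called genes. For HM-1 cells 1 of 10 splits, the real one, gave as many as 3452 genes and the highest other gave 1, and for ID8 cells 1 of 10 gave 7849 and the highest other 1. For tumors 1 of 10 gave 826 and for control tumors against control cells 1 of 10 gave 6107, with 0 genes in the highest other split of each. At an unadjusted p under 0.05 the other splits had 40 to 1592 genes in tumors and 2 to 536 in control tumors against cells, and other tools were not run on them. In all 4 the 10 splits are too few for a share under 0.05. For the difference between ID8 and HM-1 cells 1 of 50 splits gave as many as 5747 genes, with 2543 in the highest other, a share under 0.05. For tumors against HM-1 cells 2 of 50 splits gave as many as 443, a share under 0.05, but the highest other gave 809. That split kept the real labels of the cultures and put control tumor 1 with tumors 2 and 3 labelled Cd276KO, a grouping that called 0 genes by edgeR in tumors alone. The 50 splits were the real one and a random draw from the other possible splits, so each share is an estimate. Neither share excludes chance. Nor does either test the differences by itself, since a split that breaks 1 response and keeps the other also calls genes. Splits that kept the ID8 groups whole called 1439 to 2543, and in the tumor comparison those that kept the culture groups whole called 70 to 809.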

How the results depend on the processing

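Every alternative here was planned, except that gene lists without HM-1 control library 1 and without control tumor 3 were chosen only after the data were seen. No called value changed its sign. Values past no test did, among them Cd276 in ID8 cells, the tumor endothelial and pericyte medians (-0.26 and -0.09 without control tumor 3) and the HM-1 monocyte median (-0.07 without control library 1). The count of called genes changed by over 1.5 times in HM-1 cells with voom quality weights (7559) and in ID8 cells in a fit over all 18 libraries (4260). In tumors it was 2465 with DESeq2 (822 shared with the 826), 4001 over all 18 libraries and 3177 with voom weights, and DESeq2 had 37.5% false calls in the tumor simulation. Genes that differed between tumors and cells numbered 953 with DESeq2. Cd276 in tumors passed the test with DESeq2 (-0.45, adjusted p = 0.0445) and in the edgeR fit over all 18 libraries (-0.44, adjusted p = 0.00503). Genes called in the same direction numbered 104 for HM-1 and ID8 cells and 244 for HM-1 cells and tumors when calls had to exceed 2-fold, which by construction leaves fewer genes, and 1235 for HM-1 cells and tumors with DESeq2. Fry, which sets no list against other genes, ended 15 camera calls of lists in tumors (adjusted p = 0.0566 to 0.619) and added 7 in HM-1 cells (0.00117 to 0.0259) and 5 in ID8 cells (0.000739 to 0.00793). For the other changes the cause was not tested.

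Leaving out each library in turn gave 1725 to 7491 called genes in HM-1 cells, 7115 to 7877 in ID8 cells, 0 to 1685 in tumors and 4336 to 7072 for control tumors against control cells. Behind the 0, edgeR left 2851 and 2410 genes at an unadjusted p under 0.05 and DESeq2 called 1516 and 1102 without tumor 2 or 3 labelled Cd276KO. The interaction counts were 225 to 913 for tumors against cells and 4941 to 7143 for ID8 against HM-1 cells. The log2 fold change of Cd276 ranged from -0.94 to -0.80 in HM-1 cells, -0.09 to 0.01 in ID8 cells and -0.55 to -0.35 in tumors, and its differences from 0.31 to 0.55 and from 0.75 to 0.90. Of values of named genes under all alternatives, 874 stayed on their side of the threshold and 50 lost the call in HM-1 cells, 892 and 32 in ID8 cells and 410 and 254 in tumors, where 7 gained it. For gene lists the numbers were 61, 6 lost and 9 gained in HM-1 cells, 45, 13 and 5 in ID8 cells and 93, 31 and 4 in tumors.

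Replicate numbers did not pair the samples in HM-1 cells, in tumors or between control tumors and cells. Same-numbered libraries had deviations correlated at 0.011, -0.018 and 0.017 in HM-1 cells and -0.602, -0.016 and -0.096 in tumors. Between control tumors and cells the values were -0.259, 0.294 and -0.304. In ID8 cells they were 0.15, 0.037 and 0.149, against a mean of -0.056 for other pairs. There 5 of 6 libraries correlated best with their own number, so a pairing by number is not excluded in ID8 cells. With the replicate block edgeR called 2469 genes in HM-1 cells, 8329 in ID8 cells, 4694 for control tumors against cells, 69 for tumors against cells and 5401 for ID8 against HM-1 cells. In tumors it called 0, where 2726 genes had an unadjusted p under 0.05 and DESeq2 with the block called 1382. Depth limited genes at low counts, such as Cd8a and Ifng, which could not be tested.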

Other observations

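The tests per chromosome were chosen only after the data were seen, and Jun, Fosb, Il6, Cd86, Ccr7, Il2ra, Tnfrsf4, Il10, Dcn, Col1a1, Lox, Pdgfra and Hspa1b were named after their values were seen. A few members of the M1-type macrophage, immediate early and heat shock, and regulatory T cell lists were called lower in tumors labelled Cd276KO. Il1b, the gene of a cytokine of activated macrophages, fell from 62.5 ± 38.2 to 12.1 ± 2.82 CPM (n = 3 each, log2 fold change -2.36, SE 0.46, edgeR adjusted p = 0.0405). It was the 1 called member of 13 M1-type macrophage genes, and adjusted over the list alone 4 were lower, with Il6, Cd86 and Ccr7 (median -1.28, camera adjusted p = 0.00128, adjusted p = 0.548 with an estimated correlation). Among 15 immediate early and heat shock genes the phosphatase gene Dusp1 fell from 71.5 ± 48.4 to 12.3 ± 0.757 CPM and the chaperone gene Hsph1 from 231 ± 18.2 to 112 ± 21.8 CPM, with Jun also lower. Fosb joined them adjusted over the list alone (median -0.63, camera adjusted p = 0.000674, adjusted p = 0.548 with an estimated correlation). Of 8 regulatory T cell genes the costimulatory receptor gene Tnfrsf9 fell from 60.4 ± 33.8 to 12.2 ± 3.32 CPM, and adjusted over the list alone 4 were lower, with Il2ra, Tnfrsf4 and Il10 (median -1.74, camera adjusted p = 0.00218, adjusted p = 0.548 with an estimated correlation). HM-1 cells in culture also expressed Tnfrsf9, which was lower there by 1.96 on the log2 scale in libraries labelled Cd276KO. Without control tumor 3 the called members were Il1b, Cd86 and Ccr7 of the M1-type list, Dusp1, Hsph1, Jun, Fosb and Hspa1b of the immediate early and heat shock list, and Tnfrsf9 and Il10 of the regulatory T cell list, and the log2 fold changes of Il1b, Dusp1 and Tnfrsf9 were -1.67, -1.75 and -1.69, against -2.36, -2.53 and -2.29 with it. By fry the adjusted p was 0.0566, 0.0897 and 0.148 for these 3 lists. Without control tumor 2 the calls of Il1b (edgeR adjusted p = 0.0523), Dusp1 (0.0536), Hsph1 (0.0763) and Tnfrsf9 (0.0727) ended, as did those of Il1b (0.0548) and Hsph1 (0.0557) without control tumor 1. With no filter on low counts Il1b (0.10), Dusp1 (0.106) and Tnfrsf9 (0.106) lost theirs, and none held without any single tumor labelled Cd276KO (edgeR adjusted p = 0.0899 to 0.182).

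Cultured cancer cells expressed genes that the lists assign to other cell types. In ID8 cells labelled Cd276KO the collagen gene Col3a1 of the fibroblast list fell from 135 ± 10.4 to 15 ± 0.953 CPM (log2 fold change -3.10, SE 0.08), and 5 of 8 members of that list were lower and Dcn higher (camera adjusted p = 0.0259, adjusted p = 0.453 with an estimated correlation). The others lower were Col1a1, Col1a2, Lox and Pdgfra. Col1a2, at a log2 fold change of -3.49, was at -4.11 without library 2 labelled Cd276KO and lost its call in a fit over all 18 libraries (edgeR adjusted p = 0.31). In HM-1 cells Irf8, a transcription factor gene of myeloid cells, fell from 5.19 ± 0.669 to 0.369 ± 0.133 CPM (log2 fold change -3.76, SE 0.25), and Ace and Vcan fell by 6.55 (SE 0.32) and fell by 5.78 (SE 0.46) on the log2 scale.

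Genes of some chromosomes moved together in cultures labelled Cd276KO. In ID8 cells 334 of 397 tested genes of the X chromosome were lower and 23 higher, with a median log2 fold change of -0.81 (quartiles -1.089 and -0.523, camera adjusted p = 3.75e-30, adjusted p = 0.0503 with an estimated correlation). On chromosome 16, 297 of 398 were lower and 17 higher, with a median of -0.49 (camera adjusted p = 8.33e-17, adjusted p = 0.0151 with an estimated correlation). On chromosome 19, 258 of 457 were higher and 70 lower, with a median of 0.26 (camera adjusted p = 4.6e-07, adjusted p = 0.0503 with an estimated correlation). In HM-1 cells the medians were -0.32 on chromosome 15 (206 of 526 lower, 23 higher, adjusted p = 0.00202 with an estimated correlation) and -0.30 on chromosome 4 (252 of 737 lower, 19 higher, adjusted p = 0.00085 with an estimated correlation). They were 0.28 on chromosome 6 (204 of 599 higher, 44 lower, adjusted p = 0.00281 with an estimated correlation) and 0.20 on chromosome 8 (195 of 687 higher, 47 lower, adjusted p = 0.00202 with an estimated correlation). Chromosomes 12, 13, 14, 11 and 5 had medians of 0.25, -0.24, -0.25, -0.17 and 0.06 (adjusted p = 0.00985, 0.0193, 0.00985, 0.00309 and 0.0193 with an estimated correlation), and chromosome 5 missed with the preset one (camera adjusted p = 0.0819). In tumors labelled Cd276KO the medians of chromosomes 15, 4, 6 and 8 were -0.22, -0.26, 0.25 and 0.16, on the same side of 0 as in HM-1 cells (adjusted p = 0.235, 0.237, 0.088 and 0.217 with an estimated correlation). Those of chromosomes 12, 13, 14, 11 and 5 were 0.20, -0.28, -0.24, -0.14 and 0.04, also on the same side (adjusted p = 0.235, 0.167, 0.172, 0.635 and 0.088). No explanation of these shifts was tested.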
